A study of Chlorocebus aethiops with 12 samples.

How the data were processed

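Total RNA of 12 COS-1 samples was labelled with Cy3 and hybridised to 12 one-colour Agilent arrays of a human design, per the labels' protocols and the file headers. Samples were assigned to the 4 groups by their titles, 3 per group. The labels describe the 3 as biological replicates. The deposited values are intensity readings on a linear scale for 45015 spots per array, made with Feature Extraction 12.0.0.7 per the file headers (version 12 per the submitters' processing notes). Per the file headers, each array was scanned once, the local background was subtracted and the signal was detrended over the array. The deposited flags, per the file headers, mark spots that are well above background, saturated or outliers. The series-wide table deposited by the authors held the same processed intensity in all 45015 rows of each array, with no scaling between arrays. Its medians ran from 82.3 to 110.8, and its scale and direction are therefore known. It is linear and uncentred.

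The main setting was chosen before the data were examined. The processed signal was taken to log2, each array's 75th percentile over its probes was subtracted, and the 945 spots flagged as non-uniform or population outliers were set to missing. No spot was saturated. Spots of 1 probe were averaged, and the 1639 control spots were left out. Of the 41000 probes, 31236 were well above background on all 3 arrays of at least 1 group, and 31230 of these had at least 2 values in each group. The probe with the highest mean over the 12 arrays stood for its accession, which left 24586 accessions, 5284 of them with several tested probes. An accession stands in place of a gene throughout. The several probes of an accession did not always move together: of the 633 accessions with several probes and any probe called for Dex in S211A, all probes were called in 126, and 4 had probes called in opposite directions. For Dex in S211A+MDFIC these numbers were 978, 187 and 8. All probes were called in 0 of 70 such accessions for MDFIC under vehicle, 0 of 23 for MDFIC under Dex and 0 of 17 for the difference between the Dex responses.

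Groups were compared with limma 3.58.1 in R 4.3.3, by contrasts of 4 group means over all 12 arrays with moderated variances and Benjamini-Hochberg adjustment within each comparison, two-sided. An accession was called at an adjusted p under 0.05. The 5 comparisons were Dex against vehicle in S211A and in S211A+MDFIC cells, S211A+MDFIC against S211A under vehicle and under Dex, and the difference between the Dex responses. A fold marked "at least" sets the bright group's mean against the higher, array by array, of the dim probe's own signal and the lowest signal among probes well above background. Figures were drawn with matplotlib 3.10.9.

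The rule for named genes asked for symbols, which the files used here do not give. It was replaced by the 2 largest fitted rises and the 2 largest fitted falls of each comparison among called accessions whose 2 groups did not overlap, leaving out identifiers that only repeat the probe's own. No overlap criterion applied to the difference between the Dex responses. The gene lists fixed before the data were examined, and the levels of the transfected genes by symbol, were not analysed here for the same reason.

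The fit was tested on simulated arrays with the real means and spreads, in which 200 of 24510 accessions changed. For Dex in S211A, 38% of changes of log2 0.5 and 77% of changes of log2 1 were recovered, and with slide as a block 12% and 62%. For the difference between the Dex responses these shares were 22% and 68% without the block and 0% and 14% with it. For MDFIC under vehicle, 39% and 81% were recovered without the block and 0% and 39% with it. Simulated slide effects with an SD of 0.2 on the log2 scale gave 287 calls for MDFIC under vehicle, of which 178 were false, and with the block 33 calls with 1 false. For the difference between the Dex responses they gave 48 calls with 6 false, and with the block 26 with 2 false. In the real layout the block raises the standard error 1.41-fold for each Dex comparison and for their difference, and 1.87-fold for each MDFIC comparison, at equal residual variance.

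Slides were taken as possible batches, and the main fit held no term for slide. Slide 1 held the S211A vehicle arrays and S211A Dex replicate 1, slide 2 held S211A Dex replicates 2 and 3 and S211A+MDFIC vehicle replicates 1 and 2, and slide 3 held the other 4 arrays. The alternatives named before the data were examined were normexp background correction with an offset of 50, quantile normalization, median centring, the series-wide table, 2 other filters on dim probes, outlier spots kept, other ways to combine probes, trend and robust variance moderation, only the compared groups in the fit, slide as a fixed or random block, the replicate number as a block, a fold minimum of 1.5, and each array left out. The normexp setting used the median signal of a spot, since a mean signal was not among the columns used here. Since the series-wide table equals the processed signal, it was run without scaling between arrays. Array weights, the position of an array on its slide as a block, and fits within a slide were added after the data were seen.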

Results

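Genome-wide RNA levels were measured with one-colour microarrays in COS-1 cells, a fibroblast-like kidney line of the African green monkey. The cells had been transfected with S211A, a phosphorylation mutant of the glucocorticoid receptor (GR), either alone or together with MDFIC. They were then treated for 6 h with vehicle or with 100 nM dexamethasone (Dex), a synthetic glucocorticoid that activates GR. Each of the 4 groups held 3 biological replicates per the labels, which gave 12 arrays on 3 slides of 4 arrays. The series asks whether MDFIC alters transcription regulated by GR when this site of the receptor cannot be phosphorylated. The arrays carried human probes, so that the signals are those of monkey RNA on human sequences. The files give an accession for a probe but do not pair it with a gene name, so the results are given by accession, and at most 2 accessions that rose and 2 that fell are named for each comparison. The share of probes well above background was 67.8% to 71.7% on slide 1, 76.2% to 79.8% on slide 2 and 76.5% to 80.6% on slide 3. Arrays of a group correlated with r of 0.986 to 0.996 across the 24586 accessions tested. With 3 arrays per group, the number of arrays limits the precision.

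The first comparison asks which transcripts Dex changed in cells with the S211A receptor alone. Dex changed 1599 of the 24586 accessions, of which 1059 rose and 540 fell. At least 2-fold changes were mostly rises, with 195 accessions up and 12 down, and the median size of a change was 0.46 on the log2 scale. NM_000197 was not well above background on any vehicle array and lay at log2 -2.94 ± 0.03 (SD, n = 3) relative to the 75th percentile under Dex, at least 7.14-fold higher (fitted log2 5.12, SE 0.31, limma adjusted p = 9.79e-06). NM_016084 was measured on all 12 arrays and rose from -0.35 ± 0.06 to 3.29 ± 0.10 (SD, n = 3), a 12.4-fold rise (log2 3.64, SE 0.08, limma adjusted p = 2.76e-08). Its other probe showed a log2 change of 3.21. NM_018933, measured on all 12 arrays, fell by 1.58 on the log2 scale (SE 0.10, limma adjusted p = 1.02e-05). NR_038408 had a fitted log2 change of -1.61 (SE 0.25, limma adjusted p = 0.00446) but was well above background on 1 of the 3 Dex arrays.

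All 3 vehicle arrays of this comparison lay on slide 1, with 1 Dex array, and the other 2 Dex arrays lay on slide 2. With slide as a fixed block 662 accessions passed, 497 of them among the 1599, and the median change of the 1599 was 0.45. The fit without the block counts slide differences within a group as noise. The accessions it calls tend to have small ones, so that a similar median with the block is in part built in. NM_000197, NM_016084 and NM_018933 passed with the block, at log2 5.13, 3.70 and -1.58, and NR_038408 did not (log2 -1.28). With normexp background correction, whose offset shrinks changes of dim probes, NM_000197 stood at log2 1.51 and NR_038408 at -0.35, against 3.51 for NM_016084 and -1.54 for NM_018933, and NR_038408 did not pass. Within slide 1, which held all 3 vehicle arrays and 1 Dex array, 34 accessions passed, 14 higher and 20 lower, and 13 of them were among the 1599. With 1 Dex array these calls cannot be separated from the noise of that array. The balance of rises and falls depended on the scaling: centring each array on its median gave 697 rises and 654 falls, and the deposited values without scaling gave 425 and 81. The count fell to 1030 without S211A vehicle replicate 1, 1055 without vehicle replicate 2, 1040 without Dex replicate 2 and 913 without Dex replicate 3.

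The next comparison asks the same of cells that also received MDFIC. Dex changed 2457 accessions, with 1539 higher and 918 lower, and a median change of 0.40 on the log2 scale. There were 185 rises and 19 falls of at least 2-fold. NM_000197 was not well above background on any vehicle array and rose to -2.85 ± 0.06 (SD, n = 3), at least 11.7-fold (fitted log2 5.30, SE 0.31, limma adjusted p = 7.22e-06). NM_147197, likewise not well above background under vehicle, rose to -3.52 ± 0.10 (SD, n = 3), at least 7.37-fold (fitted log2 3.79, SE 0.30, limma adjusted p = 4.60e-05). Both named accessions that fell were dim. NM_001102396 was at least 2.95-fold lower under Dex, where no array was well above background (fitted log2 -2.02, SE 0.41, limma adjusted p = 0.0141). NM_001258285 fell by 1.89 on the log2 scale (SE 0.50, limma adjusted p = 0.0419) and was well above background on 2 of the 3 Dex arrays.

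**Figure D1:**
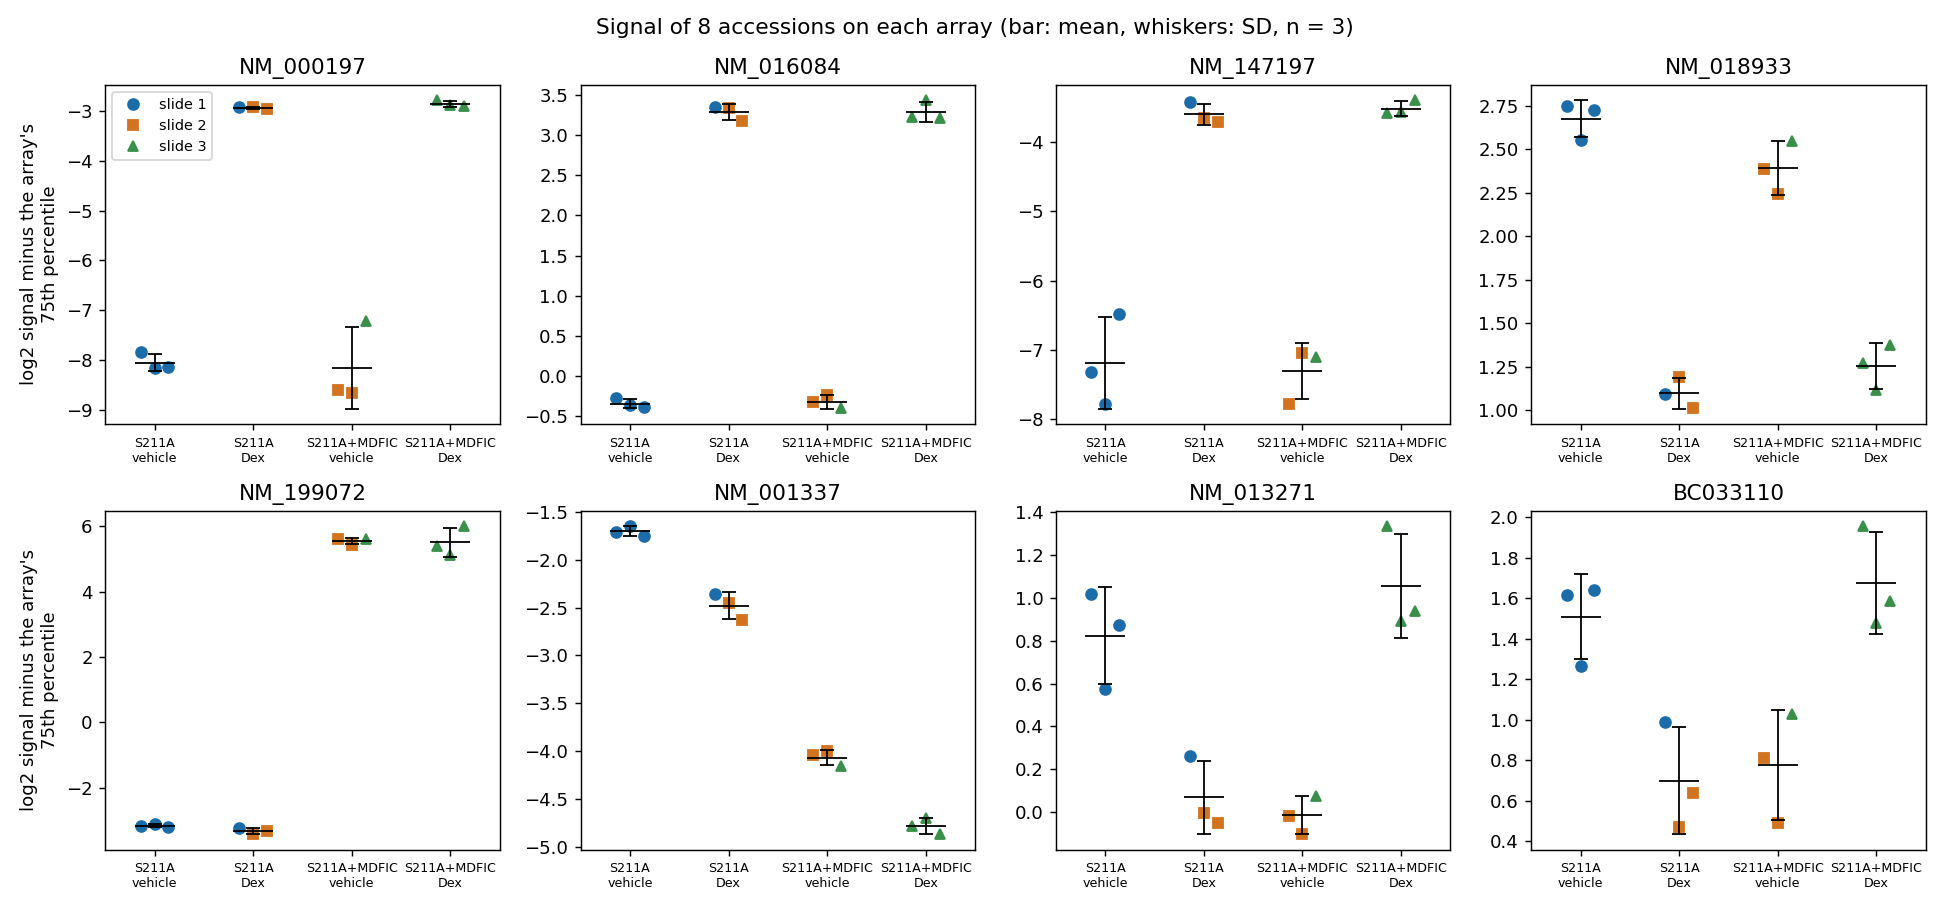
Signal of 8 accessions on each of the 12 arrays, as log2 signal minus the array's 75th percentile (y axis, with its own range in each panel) in the 4 groups (x axis). Points are arrays, with colour and shape giving the slide, bars are group means and whiskers are SD (n = 3). NM_016084 lies near -0.35 and -0.32 in the vehicle groups and near 3.29 in both Dex groups, and NM_199072 lies near -3.15 and -3.32 without MDFIC and near 5.55 and 5.51 with it.

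With slide as a fixed block the count in S211A+MDFIC cells was 597, of which 536 were among the 2457. The median change of the 2457 was 0.40 without and 0.37 with the block, all in the same direction, while the median SE rose from 0.07 to 0.10. As in S211A cells, the nearness of the medians and directions is in part built in by the choice of accessions. NM_000197 and NM_147197 passed with the block (log2 4.36 and 3.58), whereas NM_001102396 (-2.17) and NM_001258285 (-1.65) did not. With normexp these 4 dim accessions stood at 1.74, 0.99, -0.39 and -0.45, and the falls did not pass. Within slide 3, which held 3 Dex arrays and 1 vehicle array, limma called 0 accessions, with 2041 at an unadjusted p under 0.05, and the single vehicle array is assumed to vary like the others. Median centring gave 969 rises and 872 falls, and the values without scaling gave 420 and 98. Leaving out S211A+MDFIC Dex replicate 2 raised the count to 4699. Leaving out Dex replicate 1 or 3 lowered it to 1538 or 1322, and leaving out vehicle replicate 1 or 2 lowered it to 1180 or 1259.

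The Dex responses with and without MDFIC were then compared accession by accession. Of the 1065 accessions called in both, 1024 moved in the same direction. The 744 shared rises compare with 66.3 that independent lists would share, and the 280 shared falls with 20.2. The 2 comparisons share no array, and their estimation errors are uncorrelated in the fit. They do share the variance estimate of each accession, which favours accessions of low spread in both lists. Slide 2 enters both, with opposite signs. The numbers for independent lists are therefore a description and no baseline for a test. The other 41 accessions moved in opposite directions: 40 fell in S211A cells and rose in S211A+MDFIC cells. Across all accessions the correlation of the log2 changes was r = 0.44, and it was 0.21 with slide as a fixed block and 0.21 between the changes within slide 1 and within slide 3. Accessions are not independent replicates. With slide as a block, 359 accessions were called in the same direction in both.

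Accessions called as rises in S211A cells had a median log2 change of 0.53 there and 0.47 in S211A+MDFIC cells. Those called as rises in S211A+MDFIC cells had a median of 0.47 there and 0.30 in S211A cells, and each median is the larger one where the accessions were called. For falls the medians were -0.37 and -0.27, and -0.33 and -0.19. Over the 1024 accessions, which were selected for moving the same way in both, the median half-width of the 95% interval of the difference was 0.23. In limma 0 of the 1024 passed the test of the difference, and 91 had an unadjusted p under 0.05.

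**Figure D2:**
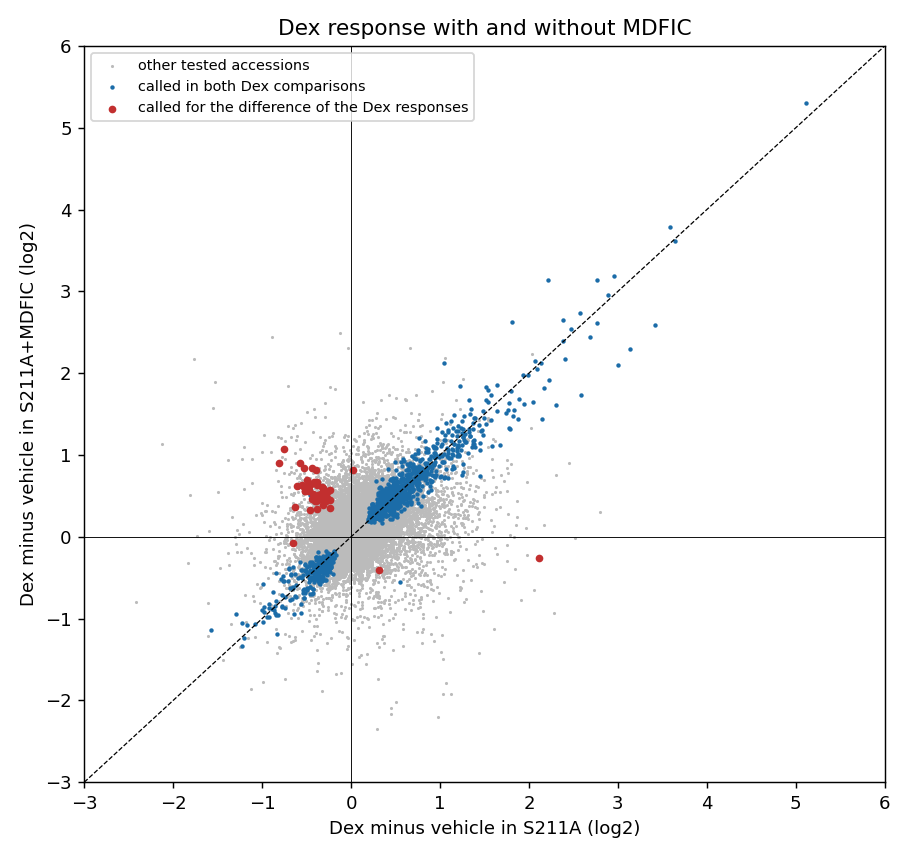
Dex minus vehicle on the log2 scale in S211A cells (x axis) against the same in S211A+MDFIC cells (y axis). Each point is 1 of the 24586 tested accessions, the dashed line marks equal responses, blue points were called in both Dex comparisons and red points passed the test of the difference. Most of the 66 red points lie at a fall in S211A and a rise in S211A+MDFIC, and most blue points lie along the dashed line.

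The test of the difference between the Dex responses, which is the interaction of Dex and MDFIC, called 66 accessions. In 64 of them the response to Dex was higher with MDFIC, and 2 went the other way. Over the 64, the median Dex change was -0.37 in S211A cells and 0.52 in S211A+MDFIC cells, and 39 were called as falls in S211A and 62 as rises in S211A+MDFIC. Their median level, relative to the mean of the 4 groups, was 0.17 in S211A vehicle, -0.21 in S211A Dex, -0.25 in S211A+MDFIC vehicle and 0.29 in S211A+MDFIC Dex. Of the 64, 51 were among the 6147 brightest accessions and all 64 were well above background on 12 arrays. NM_013271 showed a difference of 1.82 (SE 0.21, limma adjusted p = 0.0306), but 0.34 at its other probe. BC033110 showed 1.71 (SE 0.27, limma adjusted p = 0.0417). In the other direction, NM_025165 showed -0.71 (SE 0.11, limma adjusted p = 0.0464) with -0.03 at its other probe. NR_026791 showed a fitted -2.37 (SE 0.39, limma adjusted p = 0.0476), but was well above background on the 3 S211A Dex arrays and on no other array, so that the value has no measured level in the other groups.

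**Figure D3:**
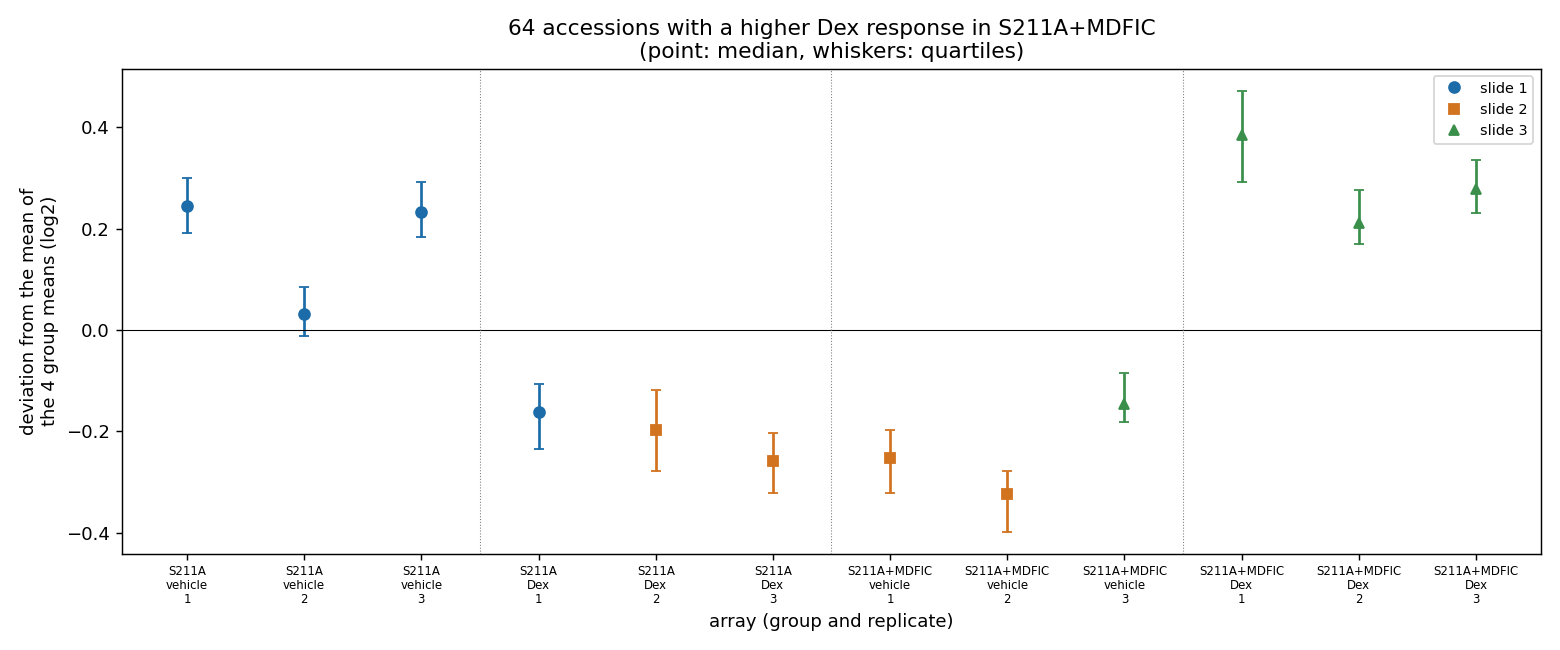
Level of the 64 accessions with a higher Dex response in S211A+MDFIC cells on each array (x axis), as the log2 deviation from the mean of the 4 group means (y axis). Points are medians over the 64 accessions, whiskers are quartiles, and colour and shape give the slide. The single S211A Dex array on slide 1 lies at -0.16, below the 3 vehicle arrays of that slide at 0.03 to 0.25, and the single S211A+MDFIC vehicle array on slide 3 lies at -0.15, below the 3 Dex arrays of that slide at 0.21 to 0.39.

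These 66 calls ended with slide as a fixed block. In limma 39 accessions then passed, and 0 of the 66 were among them, although all 66 had an unadjusted p under 0.05. The median difference of the 66 was 0.86 without and 0.74 with the block, while the median SE rose from 0.12 to 0.17. The choice of the 66 by the fit without the block also favours similar values here. NM_013271 stood at 1.54, BC033110 at 1.17, NM_025165 at -0.73 and NR_026791 at -2.27 with the block. With normexp the first 3 stood at 1.83, 1.68 and -0.65 and passed, whereas NR_026791 stood at -0.13 and did not. They also ended with the position of an array on its slide as a block (0 accessions, 2365 at an unadjusted p under 0.05), with no filter on dim probes (0 and 3320) and with the values without scaling (0 and 943). The differences of the named accessions changed little, in part by construction. Dropping the filter leaves a probe's fitted value as it is, and dropping the scaling shifts accessions measured on all arrays by the same amount. NM_013271, BC033110, NM_025165 and NR_026791 stood at 1.87, 1.72, -0.76 and -2.62 with the position block and at 1.80, 1.69, -0.73 and -2.39 without scaling, and dropping the filter left them as they were. Leaving out single arrays also took the calls across the threshold. limma called 0 accessions without S211A vehicle replicate 1 (2033 at an unadjusted p under 0.05), S211A Dex replicate 1 (2449) or replicate 3 (2140), S211A+MDFIC vehicle replicate 1 (1793) or S211A+MDFIC Dex replicate 1 (1894). Over these 5 fits NM_013271 lay between 1.68 and 1.92, BC033110 between 1.57 and 1.85, NM_025165 between -0.79 and -0.67 and NR_026791 between -2.59 and -2.02. limma called 2 without S211A vehicle replicate 3, 3 without S211A Dex replicate 2, 1 without S211A+MDFIC vehicle replicate 2 and 2 without S211A+MDFIC Dex replicate 3, and 0 of the 66 were among these calls. Thus none of the 66 passed in 9 of the 12 leave-outs. The count rose to 137 without S211A vehicle replicate 2 and to 284 without S211A+MDFIC Dex replicate 2. These 284 were 187 differences upward and 97 downward, and array weights, a setting added after the data were seen, gave 525 upward and 201 downward.

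Under vehicle, S211A+MDFIC cells differed from S211A cells in 233 accessions, 104 higher and 129 lower. NM_199072 differed most, with -3.15 ± 0.04 in S211A and 5.55 ± 0.10 in S211A+MDFIC (SD, n = 3), a 416-fold rise (log2 8.70, SE 0.18, limma adjusted p = 1.54e-08). Its other probe showed a log2 change of 0.02. Whether this accession belongs to a transfected gene was not established here. NM_001005567 was not well above background on any S211A vehicle array and was at least 7.73-fold higher with MDFIC (fitted log2 3.70, SE 0.50, limma adjusted p = 0.0101). NM_001337 fell from -1.70 ± 0.05 to -4.07 ± 0.08 (SD, n = 3), or 5.16-fold (log2 -2.37, SE 0.08, limma adjusted p = 6.96e-07). AK097877 fell by 1.39 on the log2 scale (SE 0.17, limma adjusted p = 0.00658).

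All 3 S211A vehicle arrays lay on slide 1 and the S211A+MDFIC vehicle arrays on slides 2 and 3, so that no slide holds both groups. The block takes the difference between slides 1 and 2 from the S211A Dex arrays, of which 1 lay on slide 1. It takes that between slides 2 and 3 from the S211A+MDFIC vehicle arrays. With the block 75 accessions passed, 19 of them among the 233. The 75 were 14 rises and 61 falls, and with no filter on dim probes there were 225 rises and 1231 falls. The median change of the 233 was 0.50 without and 0.49 with the block, all in the same direction, while the median SE rose from 0.07 to 0.14. This nearness is in part built in, since the fit that called the 233 favours small slide differences within a group. In S211A Dex the slide 2 arrays lay 0.022 above the slide 1 array over the 233, signed by the MDFIC effect. Over 114 accessions called from the vehicle arrays alone this was 0.0806. NM_199072 and NM_001337 passed with the block (log2 8.80 and -2.14), and NM_001005567 (2.00) and AK097877 (-1.51) did not. With normexp NM_199072, NM_001005567, NM_001337 and AK097877 stood at 8.05, 0.999, -1.65 and -0.82 and passed, so that the 7.73-fold bound for NM_001005567 holds for the deposited signals only. Without scaling there were 58 rises and 14 falls, since the S211A+MDFIC arrays were brighter by a median log2 of 0.12 over all accessions. The count was 80, 153 and 125 without S211A vehicle replicates 1, 2 and 3. It was 67, 65 and 101 without S211A+MDFIC vehicle replicates 1, 2 and 3, 132 without S211A Dex replicate 3 and 442 without S211A+MDFIC Dex replicate 2.

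Under Dex, S211A+MDFIC and S211A cells differed in 105 accessions, 65 higher and 40 lower. NM_199072 was again the highest, with a 454-fold rise (log2 8.83, SE 0.18, limma adjusted p = 1.35e-08) and -0.39 at its other probe. ENST00000454608 rose 6.96-fold, from -4.00 ± 0.33 to -1.21 ± 0.32 (SD, n = 3; log2 2.80, SE 0.18, limma adjusted p = 0.000119). NM_001337 fell 4.94-fold (log2 -2.31, SE 0.08, limma adjusted p = 1.34e-06), a fall close to that under vehicle. BX111338 was at least 1.92-fold lower with MDFIC, where it was not well above background (fitted log2 -1.20, SE 0.19, limma adjusted p = 0.0325). The MDFIC comparisons under vehicle and under Dex shared 32 rises, where independent lists would share 0.275, and 28 falls, where they would share 0.21. The comparisons share no array, but both set slide 1 against slide 3, so that constant differences between these slides would also give shared calls. Slide 2 enters the comparisons with opposite signs. The comparisons also share the variance estimate of each accession, so that independent lists are no baseline for a test. Across all accessions their log2 changes correlated with r = 0.24.

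No slide holds both groups of this comparison either. With slide as a block 12 accessions passed, 6 of them among the 105, and these 12 were 5 rises and 7 falls. The median change of the 105 was 0.60 without and 0.59 with the block, all in the same direction, while the median SE rose from 0.08 to 0.15. As under vehicle, this nearness is in part built in by the choice of accessions. NM_199072 and NM_001337 passed (log2 8.78 and -2.11), and ENST00000454608 (2.86) and BX111338 (-0.95) did not. With normexp NM_199072, ENST00000454608 and NM_001337 stood at 8.18, 2.01 and -1.31 and passed, and BX111338 stood at -0.25 and did not. Without scaling there were 29 rises and 3 falls. The count was 57 without S211A vehicle replicate 1, 36 without S211A Dex replicate 1, 45 without S211A Dex replicate 3 and 44 without S211A+MDFIC vehicle replicate 1. It was 36, 731 and 49 without S211A+MDFIC Dex replicates 1, 2 and 3.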

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

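In this part, the tests of the other probes of an accession, of the spike-in probes and of the accessions called from the vehicle arrays alone were chosen after the result was seen. The difference between the Dex responses stands out because it was tested as such and passed in 66 accessions. The named ones are NM_013271 (1.82 on the log2 scale), BC033110 (1.71), NR_026791 (-2.37) and NM_025165 (-0.71). With 3 samples per group, no test for a single outlying sample was run. Of 100 splits of the transfection labels within the vehicle arrays and within the Dex arrays, drawn from 200 and including the real one, 2 gave at least 66 accessions. Splits that mix the groups put any difference by MDFIC or by slide into the spread, which lowers their counts. The share of splits therefore cannot exclude chance for the difference between the Dex responses. No exchange of transfection labels is possible within a slide. With slide as a fixed block 0 of the 66 passed in limma, with all 66 at an unadjusted p under 0.05. The highest of the other splits gave 392, several times the real count, which points to a structure of the samples: it exchanges the transfection labels of the Dex arrays as whole groups, and so tests the MDFIC effect summed over both treatments. That sum sets slide 3 against slide 1, and with slide as a fixed block it gave 44 accessions, 18 of them among the 392.

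The 64 accessions whose Dex change was higher with MDFIC were low in S211A Dex and S211A+MDFIC vehicle, the groups that share slide 2. A lower reading of slide 2 would need -0.64, here and below as a median over all 66 calls, signed by their difference. S211A Dex arrays on slide 2 lay -0.0706 from the slide 1 array of their group, and S211A+MDFIC vehicle arrays lay -0.15 from the slide 3 array, where the same difference between arrays of 1 slide had an SD of 0.14, so a part from slide 2 cannot be told apart from array noise, and the fit that called the 66 also favours accessions with small differences of this kind. The 10 spike-in probes cannot decide on labelling yield. They were read after the scaling of each array, which removes a yield difference that they share with the sample RNA. Their difference averaged 0.0685 (SD 0.14 over probes, range -0.057 to 0.43), and labelling yield stays open. Other bright probes existed for 16 of the 66. Of these probes, 55.0% (11 of 20, exact 95% interval 31.5 to 76.9) moved the same way, against 85.4% for Dex calls. Among accessions not called the share was 58.2%. This argues against changes of whole transcripts for all of the 16, and the others were not examined. An effect of MDFIC on single transcript forms was not tested and stays open, as does a response of the probes behind the 66 calls to something other than their accession.

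Among the accessions that differed with MDFIC under vehicle, a difference of slide 1 from the others was read in S211A Dex, which is outside the comparison. To keep that group out of the choice of accessions, the 114 called from the 6 vehicle arrays alone were read, 81 of them among the 233. Over the 114, signed by the MDFIC effect, the slide 2 arrays of S211A Dex lay 0.0806 above its slide 1 array, against a median effect of 0.86 and an SD of 0.06 for the same difference within slide 3. This argues against slides 1 and 2 as the whole cause for the 114 as a set, but 64.9% of them went the way of the MDFIC effect, and over all accessions the MDFIC effect under vehicle and this slide difference correlated with r = 0.26, so that a smaller part from slides stays open, as does slide 3. Other bright probes existed for 41 of the 233. They moved the same way in 66.7% (30 of 45, exact 95% interval 51.05 to 80.0), below the 85.4% for Dex calls. Among accessions not called the share was 59.3%. This argues against changes of whole transcripts for all of the 41, and the others were not examined. The effect of MDFIC itself, on some transcripts or transcript forms, stays open. The 6 vehicle arrays allow 10 splits, too few for a share under 0.05: the real split gave 232 accessions among those measured on all arrays, 1 of the 10 splits gave as many, and the highest other gave 3.

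For the accessions changed by Dex in S211A, a difference between slides would not carry over to slide 3, where both treatments of S211A+MDFIC cells share a slide. There, 94.2% of the 1599 (1507, exact 95% interval 93.0 to 95.3) kept their direction, against 63.7% of all tested accessions. The calls of S211A+MDFIC cells, read within slide 1, kept their direction in 82.4% (52.5% of all tested), with a median of 0.20 against 0.40. Other bright probes existed for 377 of the 1599 and moved the same way in 85.6% (376 of 439), against 61.4% among accessions not called. For these 377 this goes with changes of the transcript as a whole. A response to Dex through the transfected receptor may underlie these calls. It is the design's own explanation and was not tested, since no cells without the receptor were analysed here. In 10 splits each, 1 split, the real one, gave as many accessions as observed: 1597 for Dex in S211A (highest other 0), 2452 for Dex in S211A+MDFIC (highest other 2) and 104 for MDFIC under Dex (highest other 0). These splits are too few for a share under 0.05.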

How the results depend on the processing

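Array weights, the position block and the fits within a slide were chosen after the data were seen. Of 575 values of named accessions under the alternatives, 461 kept their direction and side of the threshold, 114 kept the direction but no longer passed, and 0 reversed (limma). Many of these values could not reverse. The fitted value equals the main one with no filter on dim probes, each probe on its own, and trend and robust moderation. The same holds for only the compared groups, the replicate block, the 1.5-fold minimum, and an array left out that is outside the comparison. The tally therefore says little about direction. For the difference between the Dex responses, NM_013271, BC033110, NM_025165 and NR_026791 passed under 15, 14, 10 and 6 alternatives and not under 13, 14, 18 and 21. Counts are given in the order Dex in S211A, Dex in S211A+MDFIC, MDFIC under vehicle, MDFIC under Dex, difference of the Dex responses, and shared direction of both Dex responses, where they moved more than 1.5-fold; the cause was not tested unless stated. With slide as a fixed block they were 662, 597, 75, 12, 39 and 359, with larger standard errors by construction. With slide as a random block the MDFIC counts and the difference were 539, 223 and 153. The random block moved the named differences away from their values with the fixed block. NM_013271 stood at 1.86, against 1.82 without a block and 1.54 with the fixed one. BC033110 stood at 1.78, against 1.71 and 1.17. The larger counts therefore do not show that the calls hold once slide is taken into account. The values without scaling gave 506, 518, 72, 32, 0 (943 at an unadjusted p under 0.05) and 351. A minimum of 1.5-fold, which can only remove calls, gave 561, 616, 99 and 57, and 362 shared. Only the compared groups, with fewer arrays for the variance, gave 838, 1250, 114 and 9; the difference uses all 4 groups and has no such fit. Array weights gave 4026, 6487, 1949, 908, 726 and 1991, with the lowest weight, 0.28, for S211A+MDFIC Dex replicate 2. The position block gave 947, 1523, 46, 18, 0 (2365 at an unadjusted p under 0.05) and 661. Within slide 1, Dex in S211A gave 34, and within slide 3, Dex in S211A+MDFIC gave 0 (2041 at an unadjusted p under 0.05).

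Normexp gave 965 for Dex in S211A, 107 for MDFIC under vehicle and 125 for the difference. With no filter on dim probes, MDFIC under vehicle gave 1456, of which 1231 fell, MDFIC under Dex gave 65 and the difference 0 (3320 at an unadjusted p under 0.05). The difference was 147 with probes well above background on all 12 arrays and 36 with the mean of an accession's probes. Trend and robust moderation gave 502, 256 and 187 for the MDFIC comparisons and the difference. Leaving out 1 array gave 913 to 1871, 1180 to 4699, 65 to 442, 36 to 731, 0 to 284 and 704 to 1116. Quantile normalization, median centring, outlier spots kept and each probe on its own moved none of these counts by more than 1.5 times.

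The replicate numbers did not pair the arrays: the deviations of same-numbered arrays correlated between -0.26 and 0.25, and 4 of 12 arrays correlated best with an array of their own number. With the replicate block, MDFIC under vehicle gave 124 accessions, and the other counts stayed within 1.5 times, at 1258, 2055, 83 and 58.

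The shifts of the fixed gene lists, and the named genes by symbol, were not run under any setting. Signal over background limits the dim accessions: a probe not well above background in a group gives only a bound there, and with normexp the fold changes of these accessions lay below the bounds.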

Other observations

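The classes of accessions in this part were chosen after the data were seen. Accessions of RefSeq messenger RNAs responded to Dex more often than the other identifiers. In S211A cells 7.61% of 16443 were called, against 5.50% of 1254 Ensembl transcripts, 6.19% of 953 RefSeq non-coding RNAs and 3.71% of 5936 other sequences or probe identifiers. In S211A+MDFIC cells the shares were 11.9%, 7.74%, 6.82% and 5.69%. The odds ratio of messenger RNAs against the others was 1.84 (95% interval 1.63 to 2.09) and 2.07 (1.86 to 2.29). Within 10 strata of brightness it was 1.62 (1.43 to 1.84) and 1.54 (1.39 to 1.72). Accessions are not independent, and these intervals cover counting error only.

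With the main scaling, the balance of rises and falls under Dex differed with the brightness of the accession. It was not read by brightness under another scaling, and the difference was not tested. In S211A cells the 6147 dimmest accessions held 227 rises and 23 falls, and the 6147 brightest held 189 and 184. In S211A+MDFIC cells the dimmest held 220 and 34, and the brightest 421 and 348.

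Of the accessions called for MDFIC under vehicle, 90.1% had the same direction under Dex, against 56.3% of all tested accessions. Both comparisons set slide 1 against slide 3, so that differences between these slides would also raise this share. Slide 2 enters them with opposite signs, and a difference of slide 2 would lower it. Of the 64 accessions with a higher Dex response in S211A+MDFIC cells, 17 carry no identifier other than that of their probe. The spike-in probes lay higher relative to the 75th percentile under Dex, by 0.18 (SD 0.04 over 10 probes) in S211A and 0.25 (SD 0.13) in S211A+MDFIC cells. The arrays of both treatments overlapped in S211A but not in S211A+MDFIC cells. In S211A cells the 2 Dex arrays on slide 2 stood at 0.13 and -0.0012. The Dex array on slide 1 stood at -0.31, and the vehicle arrays of that slide at -0.31 to -0.11. In S211A+MDFIC cells Dex replicates 1, 2 and 3 stood at -0.25, -0.19 and 0.16, and the vehicle arrays at -0.42 to -0.29.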
